A study of Mus musculus with 2 samples.

How the data were processed

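H3K9me3 chromatin immunoprecipitation and sequencing was performed on liver of mouse embryos of strain B6NCrl at 15.5 days, in 2 biological replicates that pooled 78 and 62 embryos of both sexes, per the labels. The labels give the replicates separate biosamples but the same donor (strain) entry. Replicates are therefore separate pools of embryos. The files were 4 peak lists in narrowPeak format on mm10, per the deposited README files: one list per replicate, one from both replicates together (the pooled list), and one of replicated peaks derived from the pooled list and both replicates' lists. Per the same files, the replicate and pooled peaks were called from filtered alignments with 2 further input files each. The aligner, the peak caller, their versions and the replication rule are not given in the sources used here. An input control is named in the labels and was not analysed here.

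Each peak carried a fold enrichment, deposited by the authors, which is a ratio over the background of the peak caller. It also carried the −log10 of a p-value and of a q-value, deposited by the authors, and an integer display score, deposited by the authors and not used in any test. Start, end and summit offset are in bp. The smallest −log10 p was 2.01 in the lists of replicate 1, of replicate 2 (2.00) and of the pooled data, so all 3 were made with a loose threshold. Values per peak were used only to describe, rank or filter peaks within a list. No read counts or depths were in the files, so depth per replicate is unknown and precision is given as exact binomial intervals at the 95% level, which cover counting error only. No column of per-sample values was left unused except the score and the summit offset.

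Peaks on chromosomes 1 to 19, X and Y entered the tests. Replicate 1 had 282 peaks on unplaced or unlocalised contigs, replicate 2 had 282, the pooled list 296 and the replicated list 209, and these were left out of the tests. Whole lists, contigs included, were used for the list sizes, the shares at a −log10 q, the medians, the replicated share of the pooled list and the ranking by fold. Sequence and soft-masking came from the GRCm38.p6 assembly, whose chromosomes are those of mm10, and genes from GENCODE M21 (55413 genes, 21938 of them protein-coding on the 21 chromosomes). Coordinates are 1-based on mm10.

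Overlaps and permutations were computed in Python. A peak was shared when at least 50% of its length was covered by the other replicate's peaks. Chance was taken from 1000 circular rotations of peaks within the non-N sequence of each chromosome, which keep peak lengths and clustering. The p-values are permutation p-values, one-sided for overlap and clustering and two-sided otherwise. The smallest possible are 0.001 and 0.002. Gene lists were counted as members with at least 1 bp of the gene body under a replicated peak, adjusted by Benjamini-Hochberg over 25 lists. Of the listed symbols, 5 were not in the annotation (Ahsp, Hbb-b1, Hbb-b2, Ela1 and Tasor). Chromosome densities were tested by dropping domains (peaks at most 5 kb apart) at random over non-N sequence, 1000 times, adjusted over 21 chromosomes. Annotation classes used the peak midpoint, in the order promoter (within 1 kb of a gene start), exon, intron and intergenic. Position in Zfp genes was tested by 10000 random placements of each peak within its gene, and clustering by 1000 random placements within chromosomes.

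Genes and peaks were named by a rule fixed before the data were examined: up to 4 overlapped members per list by covered length, the 10 most covered protein-coding genes, the 10 replicated peaks of highest fold, the 5 longest domains, and the 3 chromosomes at each end of the density. Copies of the 31-mers of replicated peaks, and of 5 sets of rotated peaks, were counted on both strands of the 21 chromosomes. Alternatives were other overlap rules, stricter q, all pooled peaks, each replicate's own peaks, the upper 50% of replicated peaks by fold, other gene regions, length-matched random lists and clusters of genes within 50 kb counted once.

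The tests were tried on simulated data with known answers. For the gene lists, rotated peaks gave 1.22% of 1560 list tests a p under 0.05. Peaks planted in 40 of 200 random genes were all found, and that list had a permutation p of 0.01 with 200 rotations. For the chromosomes, random domains gave 7.14% of 210 tests a p under 0.05, and chromosome 5 at double density came out at 1.94 times. For the replicate overlap, 1000 planted shared peaks added 994. These checks cover the code only. Simulated nulls were drawn as the tests draw theirs, and planted peaks lay inside the genes or on the peaks counted. The simulated chromosome domains were placed at random, without the clustering of the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.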

Results

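Trimethylation of lysine 9 of histone H3 (H3K9me3), a histone mark of constitutive heterochromatin and of silenced genes and repeats, was mapped by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at 15.5 days of development. At this stage the liver is the main site of blood formation and holds hepatoblasts beside many red cell precursors. The series held 1 group with 2 biological replicates of strain B6NCrl. Replicate 1 pooled the livers of 78 embryos of both sexes and replicate 2 those of 62. No second tissue, stage or mark was part of the series, so the comparisons were between the replicates and between the peaks and the genome. The list of replicate 1 held 39679 peaks and that of replicate 2 held 42230. The authors' list from both replicates together held 36802 peaks, of which 5102 were deposited as replicated. Read depth was not given in the files, so no value below carries a sequencing depth.

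The first question was how far the peaks of the pools recurred. Most listed H3K9me3 peaks had a low significance and were found in 1 replicate. Only the few peaks with a deposited −log10 q of at least 5 were mostly found in both. On the 21 chromosomes (1 to 19, X and Y), 2736 of 39397 peaks of replicate 1 (6.94%, 95% exact binomial interval 6.70 to 7.20%) had at least 50% of their length covered by peaks of replicate 2. In the other direction, 2539 of 41948 peaks of replicate 2 (6.05%, 5.83 to 6.29%) were covered by replicate 1. Circular rotation of the peaks along each chromosome gave 0.411% and 0.364%, so the overlap was 16.9 and 16.6 times that of chance (one-sided permutation p = 0.001 for each, the smallest that 1000 rotations can give). The intervals cover counting error only.

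Recurrence rose with the significance of the peak. Among peaks of replicate 1 with a deposited −log10 q of at least 5, 123 of 138 (89.1%) were shared with the whole list of replicate 2, against 1947 of 34963 (5.57%) of those below 1. The corresponding shares for replicate 2 were 156 of 210 (74.3%) and 1493 of 33975 (4.39%). Peaks below 1 thus made up 1947 of the 2736 shared peaks of replicate 1 and 1493 of the 2539 of replicate 2. This split by q was chosen after the data were seen. Peaks with a −log10 q of at least 2 made up 3.84% of the list of replicate 1 and 4.50% of that of replicate 2. Across the 2736 shared peaks, the authors' fold enrichment of the replicates was weakly related, with Spearman's rho of 0.273 and Pearson's r of 0.379 on the log2 scale. These are correlations across peaks, which are not independent replicates.

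**Figure D1:**
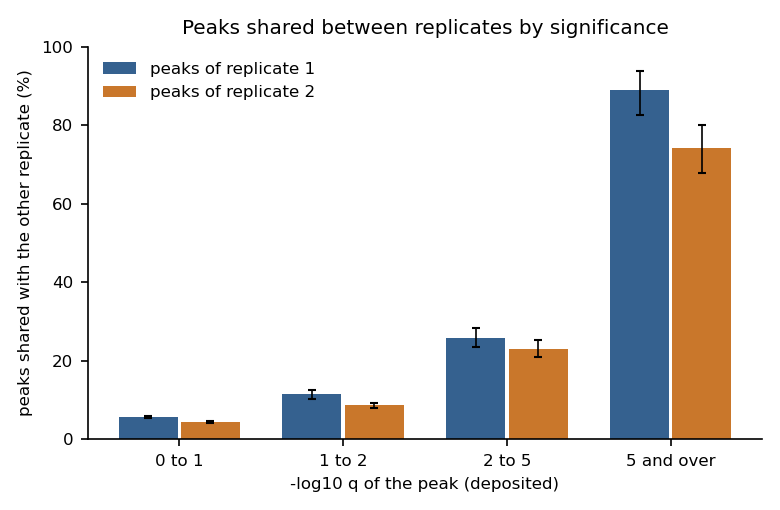
Percent of each replicate's peaks with at least 50% of their length covered by the other replicate's peaks, by the peak's deposited −log10 q. Bars are shares and error bars their 95% exact binomial intervals; the shares go from 5.57% to 89.1% for replicate 1 and from 4.39% to 74.3% for replicate 2.

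The replicated list concentrated the stronger and longer peaks of the pooled list. It kept 13.9% of the pooled peaks (95% exact binomial interval 13.5 to 14.2%), 695 of the 726 with a −log10 q of at least 5 (95.7%), and 312 of the 15076 below 1 (2.07%). These counts include contigs outside the chromosomes. On the 21 chromosomes alone the share was 13.4%, and 551 of the 695 lay there. Of the pooled peaks of 500 bp and longer, 1069 of 1230 (86.9%) were replicated. Replicated peaks had a median length of 342 bp and a median fold enrichment of 3.13, against 215 bp and 2.77 for all pooled peaks. The rule behind the list is not given in the sources used here. All 2786 pooled peaks with at least 50% of their length covered in each replicate's list were among the replicated peaks, while 957 of the 4893 replicated peaks on the 21 chromosomes (19.6%) had no overlap at all in at least 1 replicate's list.

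The next question was where in the genome the replicated peaks lay. Chromosomes 5, 4 and 17 held the most per Mb of non-N sequence, and Y, X and 14 the fewest. Chromosome 5 had 665 peaks, 4.50 per Mb and 2.43 times the number expected from random placement of the domains over the genome. Chromosome 4 had 506 peaks (3.33 per Mb, 1.81 times) and chromosome 17 had 263 (2.87 per Mb, 1.56 times). Chromosome 14 had 121 peaks (1.00 per Mb, 0.544 times), the X had 52 (0.318 per Mb, 0.173 times) and the Y had 8 (0.0908 per Mb, 0.0491 times). Each of these 6 had a two-sided permutation p of 0.002, the smallest that 1000 placements can give, and a Benjamini-Hochberg adjusted p of 0.0042. Domains were placed independently, although 56.5% of replicated peaks had another within 50 kb, against 20.8% after random placement within each chromosome. The chromosome p-values may therefore be too small. In all, 5 chromosomes were above and 8 below expectation at an adjusted p under 0.05. Among the 551 replicated peaks with a −log10 q of at least 5, 0 chromosomes passed and 4 had an unadjusted permutation p under 0.05 (chromosomes 3, 9, 14 and Y). There the ratio was 1.21 for chromosome 5, 1.63 for chromosome 4, 1.86 for chromosome 17, 0.401 for chromosome 14, 0.729 for the X and 0.384 for the Y. In the own lists of replicates 1 and 2, chromosome 5 was at 1.56 and 1.71 times, chromosome 4 at 1.20 and 1.26 times and chromosome 14 at 0.903 and 0.869 times expectation, and the Y at 0.00687 and 0.00931 times. For the Y, no test of multi-copy sequence or of dose in pools of both sexes was run. The low count of the Y was therefore not told apart from these. Of the 52 peaks on the X, 23 lay in its last 1.13 Mb of non-N sequence, which holds Mid1 and Asmt, and so did 15 of the 25 X peaks with a −log10 q of at least 5.

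**Figure D2:**
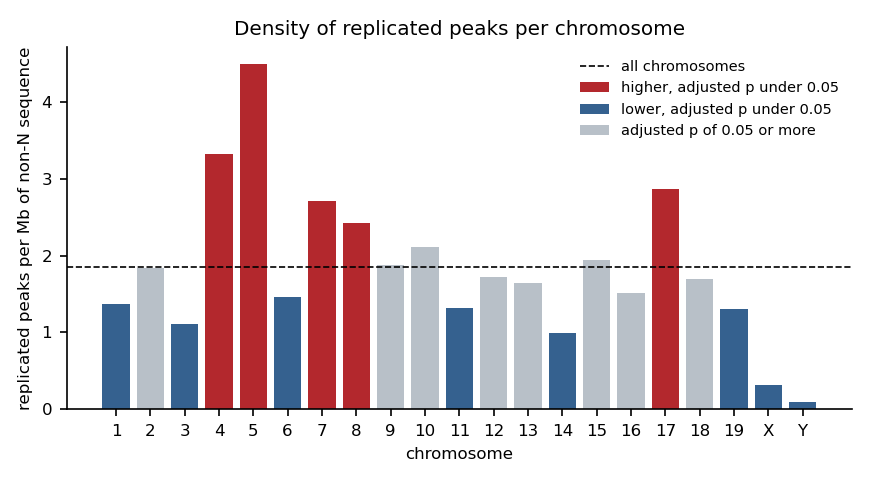
Replicated peaks per Mb of non-N sequence on each chromosome (bars) and over all chromosomes (dashed line, 1.85 per Mb). Colours mark chromosomes above or below random placement at an adjusted permutation p under 0.05; chromosome 5 is highest at 4.50 per Mb and the Y lowest at 0.0908.

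H3K9me3 peaks lay close to each other. Of the 4893 replicated peaks, 1904 (38.9%) had another within 10 kb, against 4.78% after random placement within each chromosome, an 8.14-fold excess (one-sided permutation p = 0.001, the smallest possible). In replicate 1's own list the share was 52.0% against 28.7% (1.81-fold), and in replicate 2's it was 53.3% against 30.4% (1.75-fold). Over all pooled peaks it was 58.1% against 27.9% (2.08-fold). At a −log10 q of at least 5 it was 43.2% against 0.499% (86.5-fold). The share after random placement rises with the number of peaks, so these ratios do not compare the strength of clustering between lists. Merging peaks at most 5 kb apart gave 3844 domains, of which 531 held several peaks. The longest domain spanned 43.7 kb on mm10 chromosome 1 (88211847 to 88255546). It held 27 peaks over the shared 3′ end of the Ugt1a genes, which encode bile and drug conjugating enzymes, and over Mroh2a. The highest fold among these peaks was 2.95, below the median of 3.13 over all replicated peaks. The second spanned 35.8 kb on chromosome 17 (13206437 to 13242285) over Smok2a and Smok2b, sperm motility kinase genes. The third (23.2 kb, chromosome 9, 3015151 to 3038369) and the fourth (22.5 kb, chromosome 4, 3050453 to 3072912) lay near the chromosome starts. All 17 peaks of the third had 31-mers present at 2 or more places in the assembly. The fifth (21.5 kb, chromosome X, 169978353 to 169999803) lay in Mid1, a ubiquitin ligase gene that straddles the pseudoautosomal boundary, and 10 of its 12 peaks were of such multi-copy sequence.

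The highest fold enrichment was in Asmt, the pseudoautosomal gene of the last step of melatonin synthesis. Its peak at 170674164 to 170675431 on the X had a fold enrichment of 10.03 in the pooled data, 9.22 in replicate 1 and 8.36 in replicate 2, and a neighbouring peak had 9.44. Both lay in introns. Next among placed peaks came an exonic peak of Trim56, an antiviral ubiquitin ligase gene, on chromosome 5 (137112419 to 137114929) with a fold of 8.16. A peak on the Y at 259019 to 259462 had 7.53 and was of multi-copy sequence, 537947 bp from the nearest protein-coding gene start, that of Zfy1. An intergenic X peak (150366880 to 150367539) 91615 bp from the start of Tmem29 had 7.26, a chromosome 17 peak (56493946 to 56495337) 17094 bp from the start of Znrf4 had 7.22, and an intronic peak of Kdelr2 (chromosome 5, 143413655 to 143413986) had 6.92. The remaining 3 of the 10 strongest lay on contigs outside the chromosomes.

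Promoters and exons held more replicated peaks than rotation gave, and introns fewer. Within 1 kb of a gene start lay 293 peak midpoints (5.99%, 1.501 times the rotation mean) and in exons 358 (7.32%, 1.77 times). Introns held 1619 (33.1%, 0.789 times). Each of these had a two-sided permutation p of 0.002, the smallest possible. The 2623 intergenic peaks (53.6%, 1.07 times) did not pass (permutation p = 0.0579). Protein-coding genes held 315 of the 358 exonic peaks, and 94 of the 358 were in zinc finger (Zfp) or clustered protocadherin genes. Against rotated positions of the same GC content, a comparison chosen after the data were seen, promoters were at 1.11 times (95% interval 0.958 to 1.28), and over all pooled peaks exons were at 0.981 times rotation (permutation p = 0.715). At a −log10 q of at least 5, promoters were at 2.81 times and exons at 3.42 times rotation (permutation p = 0.002 for each). In the list of replicate 1, promoters were at 0.896 times (permutation p = 0.004) and exons at 0.808 times (permutation p = 0.002) the rotation mean. In that of replicate 2, promoters were at 1.21 times (permutation p = 0.002) and exons at 0.987 times (permutation p = 0.753).

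The sequence of replicated peaks was richer in GC and CpG than rotated positions, and held less soft-masked and less multi-copy sequence. GC content was 48.2% against 42.1% after rotation. The observed over expected CpG ratio was 0.266 against 0.195, and the soft-masked share was 25.2% against 33.9% (permutation p = 0.002 for each, two-sided, the smallest possible). In replicate 1's own peaks the CpG ratio fell below rotation, at 0.961 times (permutation p = 0.002). Only 100 of the 4893 replicated peaks (2.04%) had a median of 2 or more genomic copies of their 31-mers, against 14.0% of rotated peaks. Among peaks of copy number 1, the soft-masked share was 24.4%, against 26.0% for rotated peaks, so most of the gap in soft-masked sequence lay in multi-copy positions. Rotation also reaches positions where reads may not be placed. The deficit in multi-copy and soft-masked sequence is therefore not shown to belong to the mark.

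The final question was which genes lay under H3K9me3. Replicated peaks overlapped 968 of 21938 protein-coding genes (4.41%). Of 25 gene lists fixed before the data were examined, 4 were overlapped more than rotation gave: Zfp genes, clustered protocadherins, imprinted genes and germline genes. No other list had an unadjusted permutation p under 0.05.

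Zfp genes encode C2H2 zinc finger proteins, many of them KRAB repressors of transposable elements. A replicated peak overlapped 62 of 394 (15.7%), against 17.9 after rotation, a 3.47-fold excess (two-sided permutation p = 0.002, adjusted p = 0.025). Chromosome 7 held 20 of the 62, of the 92 Zfp genes that lie on it, and chromosome 4 held 7, of 30. The most covered were Zfp873 on chromosome 10 (82048123 to 82064745), with 7 peaks over 4027 bp, and Zfp981 on chromosome 4 (146502027 to 146539395), with 10 peaks over 3886 bp. Zfp936 on chromosome 7 (43114229 to 43192109) had 10 peaks over 3716 bp. Zfp180 on chromosome 7 (24081924 to 24107713) had a single peak of 3709 bp in its last exon, with a fold of 5.30 in the pooled data, 5.55 in replicate 1 and 6.10 in replicate 2. With 1 gene per cluster, 48 of 248 were overlapped (2.88-fold, permutation p = 0.002, adjusted p = 0.05), and at a −log10 q of at least 5 the excess was 10.5-fold (adjusted permutation p = 0.025). In the own peaks of replicate 1 the list was at 1.2502 times rotation (adjusted permutation p = 0.362), and at gene starts it was not called, with 4 genes (2.06 times, adjusted permutation p = 1).

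Within Zfp genes the mark sat towards the 3′ end, where the exon coding for the zinc finger array lies. Of 145 peaks in the 62 genes, 65 (44.8%) had their midpoint in the last of 5 equal parts of the gene body, against 20.1% for random placement within the same gene (two-sided permutation p = 0.0002, the smallest that 10000 draws can give). From the start of the gene, 5 equal parts held 5, 19, 14, 42 and 65. The last exon held 73 of the 145 (50.3%, 2.77 times random placement, permutation p = 0.0002). These tests placed each peak independently, although the 145 peaks came from 62 genes, so their p-values do not measure variation between genes.

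**Figure D3:**
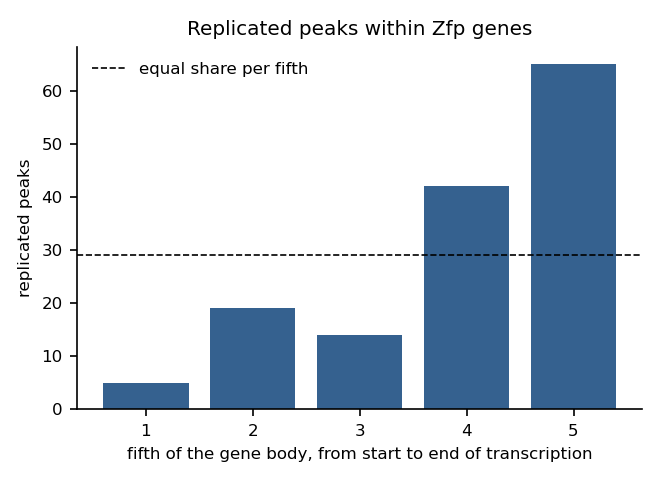
Number of replicated peaks with their midpoint in each of 5 equal parts of a Zfp gene body, from the start to the end of transcription; the dashed line is an equal share of the 145 peaks. Counts are 5, 19, 14, 42 and 65.

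Clustered protocadherins, cell surface adhesion proteins that give neurons their identity, lie in tandem on chromosome 18. A peak overlapped 39 of 57 (68.4%), against 5.67 after rotation (6.88-fold, two-sided permutation p = 0.004, adjusted p = 0.025). The locus (36930184 to 37841873) held 26 peaks with a median fold of 3.198, and 20 of them were in exons. Pcdha1 had 8 peaks, Pcdha2 had 7, Pcdha3 had 5 and Pcdha4 had 4, and since these gene models share their 3′ exons, a peak can count for several. No member was overlapped by a peak with a −log10 q of at least 5, and as 3 clusters instead of 57 genes, all 3 were overlapped (5.40-fold, permutation p = 0.03, adjusted p = 0.188). In the own lists the ratio was 1.81 for replicate 1 (adjusted permutation p = 0.175) and 2.04 for replicate 2 (adjusted permutation p = 0.0333), and the call was also lost in the upper 50% of peaks by fold (4.77-fold, adjusted permutation p = 0.73) and with at least 500 bp covered (13.7-fold, adjusted permutation p = 0.07).

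Imprinted genes, expressed from one parental allele, were overlapped in 14 of 49 cases (28.6%), against 4.403 after rotation (3.18-fold, two-sided permutation p = 0.002, adjusted p = 0.025). At Gnas, the stimulatory G protein gene on chromosome 2 (174284320 to 174346744), 6 peaks covered 4101 bp, the strongest with a fold of 4.29 (4.13 and 4.50 in replicates 1 and 2). Its antisense transcript Nespas had 2 peaks. Cdkn1c, a growth-restraining cell cycle inhibitor on chromosome 7 (143458339 to 143461050), had a promoter peak of 1480 bp with a fold of 4.67, 4.13 in replicate 1 and 6.32 in replicate 2. Mest on chromosome 6 had 2 intronic peaks, the stronger with a fold of 3.98. Among these genes, 7 had a peak within 1 kb of the start, against 0.210 after rotation (33.3-fold, adjusted permutation p = 0.0167). Counted as 29 clusters, 9 were overlapped (2.27-fold, permutation p = 0.012, adjusted p = 0.10). In the own list of replicate 1 the ratio was 1.38 (adjusted permutation p = 0.362) and in that of replicate 2 it was 1.83 (adjusted permutation p = 0.0333).

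Germline genes, active in germ cells and silent in somatic tissue, were overlapped in 7 of 40 cases (17.5%), against 1.83 after rotation (3.82-fold, two-sided permutation p = 0.004, adjusted p = 0.025). Promoter peaks marked 5 of them, against 0.178 after rotation (28.1-fold, adjusted permutation p = 0.0167). Dazl, an RNA-binding regulator of germ cells, had a promoter peak of 1129 bp on chromosome 17 (50293024 to 50294152) with a fold of 4.32, called in replicate 1 at 4.13 and in replicate 2 at 3.85. Promoter peaks at Ddx4, the germ cell RNA helicase, and Taf7l, a testis TFIID subunit on the X, had folds of 3.28 and 3.46 in the pooled data and were called in the list of replicate 2 but not in that of replicate 1. Tdrd9, a piRNA pathway helicase, had an intronic peak at 3.78. In each replicate's own list, whole germline genes were overlapped at 0.728 (replicate 1) and 0.865 times (replicate 2) the rotation mean, neither called (adjusted permutation p = 0.696 and 1), and over all pooled peaks at 1.17 times (adjusted permutation p = 1). The call was also lost in the upper 50% of peaks by fold (4 genes, 3.64-fold, adjusted permutation p = 0.432) and at a −log10 q of at least 5 (1 gene, 5.10-fold, adjusted permutation p = 1), and with 2 kb added on each side (3.46-fold) or 1 gene per cluster (3.82-fold) the adjusted permutation p was 0.05.

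**Figure D4:**
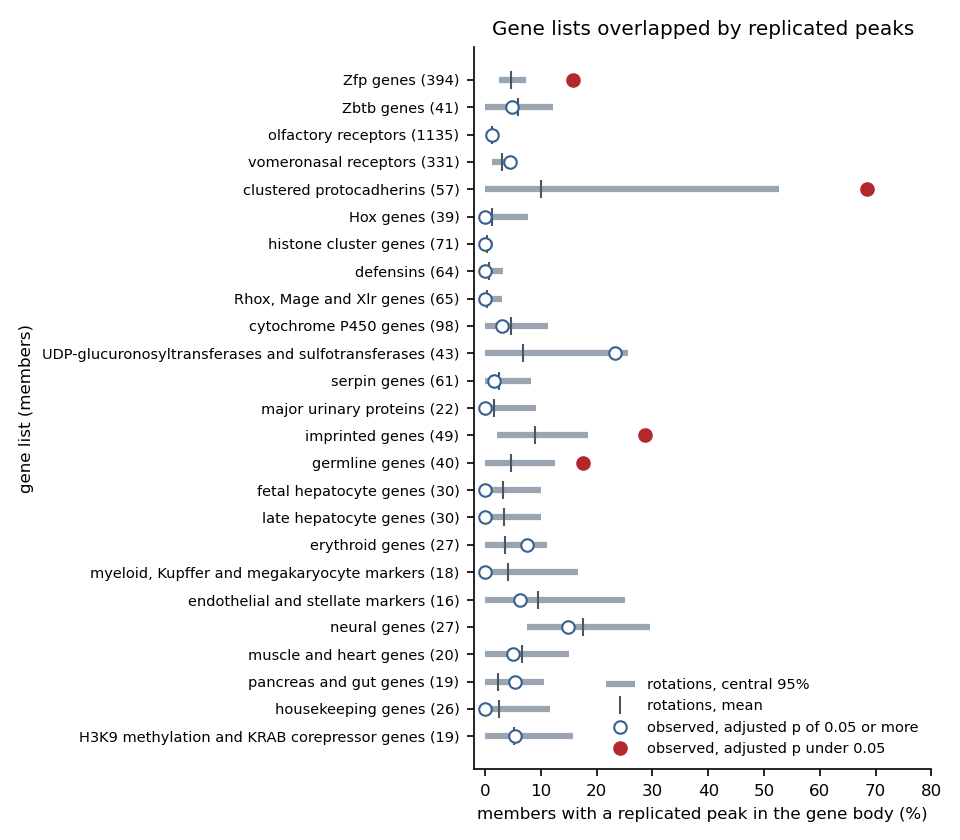
Percent of each list's members with a replicated peak in the gene body (circles), with the mean of 1000 rotations (tick) and their central 95% (grey bar). Filled circles are the 4 lists at an adjusted permutation p of 0.025: Zfp genes at 15.7%, clustered protocadherins at 68.4%, imprinted genes at 28.6% and germline genes at 17.5%.

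Genes of the liver's own cell types had few or no peaks, but with so few expected per list a depletion was not detectable. None of 30 fetal hepatocyte genes (0.969 expected, permutation p = 0.719) and none of 30 late hepatocyte genes (1.02 expected, permutation p = 0.713) was overlapped. The same held for 18 myeloid, Kupffer and megakaryocyte markers (0.744 expected, permutation p = 0.923) and 26 housekeeping genes (0.639 expected). Of 27 erythroid genes, 2 were overlapped (0.978 expected, permutation p = 0.517). Zfpm1, the cofactor of GATA1 known as FOG1, had a peak of 1801 bp in a 3′ exon at a fold of 5.18, and Bcl11a, the fetal globin repressor, had an intronic peak at 3.25. The endothelial and stellate list had 1 of 16 (1.51 expected), Reln, with a promoter peak at 3.11. Over all pooled peaks more overlaps were expected, and none of these lists was called after adjustment. There fetal hepatocyte genes had 1 (5.2 expected, permutation p = 0.0539, adjusted p = 0.25) and late hepatocyte genes 4 (5.1 expected). Housekeeping genes had 0 (3.5 expected, permutation p = 0.032, adjusted p = 0.2).

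Drug-metabolising families were mixed. Of 43 UDP-glucuronosyltransferase and sulfotransferase genes, 10 were overlapped (2.90 expected, 3.44-fold, permutation p = 0.0919, adjusted p = 0.46). Of these, 9 were Ugt1a genes, which share their 3′ exons, and Ugt1a7c, Ugt1a10, Ugt1a5 and Ugt1a6a each had 8 or 9 peaks with a top fold of 4.10. With only peaks of −log10 q of at least 5 the list passed at 34.4 times rotation (adjusted permutation p = 0.0333), with 9 genes. Counted as clusters over all replicated peaks, 2 of 25 were overlapped (1.97 expected, 1.01-fold, adjusted permutation p = 1), and against random lists matched on gene length the list passed (5.27-fold, adjusted permutation p = 0.00125). Those random lists drew genes independently, so that p does not allow for peaks shared by the 9 Ugt1a genes. Cytochrome P450 genes had 3 of 98 (4.46 expected), namely Cyp20a1, Cyp3a16 and Cyp2j8. Serpins had 1 of 61 (1.497 expected), Serpinf2, and the 22 major urinary protein genes had 0 (0.332 expected).

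Other tandem families and genes of other tissues were near chance. Olfactory receptors were overlapped in 14 of 1135 cases (13.2 expected), among them Olfr115, Olfr769, Olfr137 and Olfr1491, and vomeronasal receptors in 15 of 331 (10.1 expected), among them Vmn1r42, Vmn2r60, Vmn2r95 and Vmn2r53. Zbtb genes had 2 of 41 (2.41 expected), Zbtb22 with an exonic peak at a fold of 5.71 and Zbtb46 with an intronic one at 3.79. No peak overlapped the 39 Hox genes, 71 histone cluster genes, 64 defensins or 65 Rhox, Mage and Xlr genes, for which rotation gave 0.442, 0.173, 0.409 and 0.211. Neural genes had 4 of 27 (4.76 expected): Slc17a7, Csmd1, Dlgap1 and Ctnna2. In the muscle and heart list 1 of 20 was overlapped (1.31 expected), Ttn, the giant sarcomere gene, with 14 peaks that all lay in exons. Vil1 was the 1 of 19 pancreas and gut genes (0.441 expected) and Atf7ip, a cofactor of the H3K9 methyltransferase SETDB1, the 1 of 19 genes of the H3K9 methylation list (0.968 expected).

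By covered length, the leading protein-coding gene was Mroh2a next to Ugt1a, with 18646 bp but a top fold of only 2.95 (−log10 q of 9.57). It was followed by Tmem132d on chromosome 5 (18607 bp in 48 peaks, 47 of them intronic) and the adhesion gene Cdh13 on chromosome 8 (17257 bp in 47 peaks, all intronic). Tmem132b on chromosome 5 (11462 bp in 28 peaks) and the ciliary gene Nphp4 on chromosome 4 (8511 bp in 11 peaks) also ranked among the first 10. Drg1 (11855 bp) and Sfi1 (9964 bp) overlap on chromosome 11 and shared a peak (3190995 to 3195381) with a fold of only 3.44 but a −log10 q of 109. The other 3, Gm20388 (9094 bp), Gm42416 (8711 bp) and Gm37013 (8422 bp), are gene models spanning several genes, the last 2 across the protocadherin locus.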

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

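Of the replicated peaks, 209 (4.10%) lay on contigs that are not placed in a chromosome, which the tests of chromosomes, annotation, sequence and gene lists did not use; a count of 0 would allow up to 3. They were found on 18 of 44 such contigs, which hold 5.33 Mb in the assembly, or 39.2 peaks per Mb, 21.2 times the density on the chromosomes (95% exact interval 18.4 to 24.4). That interval covers counting error only, not the spread between contigs. Of the pooled contig peaks, 209 of 296 (70.6%, 65.1 to 75.7%) were replicated, against 13.4% on the chromosomes. Their median fold enrichment was 2.84, against 3.15 on the chromosomes. The unplaced contig JH584304 had 64 of them, followed by GL456383 with 27, and the strongest (fold 9.64) was on GL456216, a contig assigned to chromosome 4. No explanation of it was tested.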

How the results depend on the processing

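The GC-matched counts, the counts at copy number 1, those without Zfp and protocadherin genes and the split of the overlap by q were chosen after the data were seen; the other alternatives were fixed before the data were examined. Replicate overlap, the soft-masked and GC shares, clustering and the position in Zfp genes kept their direction and passed under each alternative run on them. The clustering ratio went from 1.75 (without replicate 1) to 86.5 (−log10 q of at least 5), but it depends on the number of peaks in the list. The shared percentage went from 5.23 to 65.2 for replicate 1 and from 4.91 to 43.3 for replicate 2 (50% of both peaks, and −log10 q of at least 5). Main results that changed call or moved by over 1.5 times are as follows. Lists and chromosomes that turned direction are also given, where the main result or the alternative was called. Uncalled ones that turned direction are not listed. Single ones that only lost or gained the call are counted at the end. The cause was not tested unless stated. At an overlap of at least 1 bp, rho was 0.220. The replicated share was 52.3% for pooled peaks with −log10 q of at least 2 and 7.63% when 50% of the peak had to be covered in each replicate's list. With −log10 q of at least 5 (551 peaks), 0 of 21 chromosomes passed (4 at an unadjusted permutation p under 0.05). At that threshold promoters were at 2.81, exons at 3.42, CpG at 2.06, Zfp genes at 10.5, introns at 0.883 and intergenic sequence at 0.763 times rotation, chromosome 8 at 0.879 and chromosome 11 at 1.19 times expectation, and protocadherins at 0. Over all pooled peaks, Zfp genes were at 1.52, exons at 0.981 and intergenic sequence at 1.21. Against rotated positions of the same GC content, promoters were at 1.11. With 1 gene per cluster, 0 lists passed (4 at an unadjusted permutation p under 0.05) and the Zfp ratio was 2.88, with germline genes still at 3.82. Both had an adjusted p of 0.05; over 25 lists a single list at 0.002, the smallest permutation p, cannot fall below that, so the number of rotations limits this count. The Zfp ratio was 2.06 within 1 kb of gene starts and 7.70 with at least 500 bp covered. The higher-fold 50% of peaks gave 2 lists. In the lists without replicate 1 or without replicate 2, the lists called ranged from 0 to 3 and the Zfp ratio from 1.2502 to 1.37. Promoters ranged from 0.896 to 1.21, exons from 0.808 to 0.987, intergenic sequence from 1.17 to 1.24, CpG from 0.961 to 1.11, protocadherins from 1.81 to 2.04, imprinted genes from 1.38 to 1.83 and germline genes from 0.728 to 0.865. Chromosome 5 ranged from 1.56 to 1.71, chromosome 14 from 0.869 to 0.903, chromosome 1 from 0.984 to 1.02, chromosome 3 from 0.902 to 1.01, chromosome 9 from 0.918 to 0.965 and chromosome 16 from 0.987 to 1.097. Of the 366 alternatives on single lists and chromosomes, 316 kept direction and call or stayed uncalled whatever their direction, 28 lost the call, 13 gained it and 9 turned direction by the rule above. Those that gained it were chromosomes 10, 13, 15 and 16 and the UDP-glucuronosyltransferase and sulfotransferase list. Read depth is unknown, so what it limits cannot be given.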

Other observations

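The tests of the X before its last part, of own peaks off the replicated ones and of 1 dense window alone were chosen after the result was seen, and so were the GC-matched, copy-number-1 and family-removed counts as alternatives and the genes of the dense windows named here. The design has 1 group, so no biological explanation was tested for any pattern.

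Replicated peaks were dense in a few 1 Mb windows. On chromosome 4, 153 to 154 Mb held 74 peaks, of which 16 lay in Ajap1. On chromosome 5, 116 to 117 Mb held 59, 127 to 128 Mb held 59 (24 in Tmem132d and 15 in Tmem132c) and 125 to 126 Mb held 52 (28 in Tmem132b). A further window of chromosome 4, 147 to 148 Mb, held 46, of which 3 lay in Zfp982. A window of chromosome 2, 171 to 172 Mb, held 45 peaks and no protein-coding gene, and 118 to 119 Mb of chromosome 8 held 43, 32 of them in Cdh13. Promoter peaks of the imprinted list, chosen here after their values were seen, also lay at Peg3 and Usp29 (1 peak, fold 2.37), Meg3 (3.11) and Airn (3.15), and those of the germline list at Sycp1 (3.11) and Stag3, a meiotic cohesin gene (2.995).

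The 5 densest windows on chromosomes 4 and 5 held 290 peaks. The tables argue against multi-copy sequence over the windows together and against peaks of 1 replicate only. The count in the windows was 24.6 times (95% interval 21.9 to 27.6) that expected from other bins of the same GC content. The windows were picked by this same count, so a ratio above 1 was fixed in advance. Its interval covers counting error only, and GC content stays open. Of the windows' peaks, 2.76% (1.20 to 5.36%) were multi-copy. All 8 multi-copy peaks lay in 147 to 148 Mb of chromosome 4, where they were 17.4% (7.82 to 31.4%), so that multi-copy sequence stays open for that window. Density in the windows was 10.3 times that elsewhere in replicate 1's own list (9.60 to 11.1) and 12.8 times in replicate 2's, of which 3.58 and 3.72 come from peaks on the replicated peaks by which the windows were picked; among own peaks that overlap none of these it was 7.58 (6.92 to 8.28) and 10.2 times. A copy number difference of the strain was not tested and stays open.

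The X held few replicated peaks, and 23 of its 52 lay in its last part. Against autosomal bins of the same GC content the count was 0.205 (95% interval 0.153 to 0.268), and per unmasked Mb the ratio was 0.197 (0.147 to 0.259), which argues against GC content and repeats as the cause. A lower dose of the X in pools of both sexes cannot be told apart, as the upper bounds lay above 0.5. At −log10 q of at least 2 the X had 0.720 (0.506 to 0.998) of the autosomal density at −log10 q of at least 4, and the X before its last part had 0.363 (0.217 to 0.570). These cutoffs took the X at the dose of a male, with a −log10 q of 4 falling to 2. Pools of both sexes hold more X than that, which made the comparison lenient towards dose. Peaks of lower q were also replicated less often, which made it stricter. Of the pooled peaks, 52.3% were replicated at −log10 q of at least 2 and 95.7% at −log10 q of at least 5. These effects go opposite ways, so the comparison cannot decide. At −log10 q of at least 5 the whole X had 0.706 of the autosomal density (0.453 to 1.05) and the X before its last part 0.284 (0.136 to 0.527).

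Peaks were more frequent in promoters and exons than rotation gave. For promoters, GC content cannot be told apart, with a count of 1.11 (95% interval 0.958 to 1.28) times that of rotated positions of the same GC content, an interval that holds 1. For exons, the ratio was 1.49 (1.30 to 1.69) at the same GC content and 1.69 (1.47 to 1.92) among peaks and positions of copy number 1, which argues against either as the whole cause. Without Zfp and protocadherin genes it was 1.36 (1.13 to 1.58). That interval lay above 1, which argues against those families as the whole cause, though its lower bound missed the limit set before the test. Over all pooled peaks the exon ratio was 0.981.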
